A study of Mus musculus with 14 samples.

How the data were processed

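The series profiled histone H3 lysine 27 acetylation (H3K27ac), a mark of active promoters and enhancers, in CD11b+ macrophages sorted by flow cytometry from brain tumours of mice. The assay was CUT&Tag, in which an antibody guides a transposase that cuts and tags the DNA beside the mark. There were 14 libraries: 3 with H3K27ac antibody from vehicle-treated mice, 4 with H3K27ac antibody from pracinostat-treated mice, and as many with non-specific IgG, which gives the background of the assay. Per the labels' protocols, cells were fixed with 0.1% formaldehyde and a target depth was set for each library. The reads obtained per library are not given in the sources used here, so the depth behind each value is known only through the number of summits.

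Each library had 1 deposited file, a list of peak summits (single bases at the top of a peak) with a −log10 significance value per summit. Per the submitters' processing notes, Bowtie2, MACS2 2.2.9.1, DESeq2 and HOMER were used with the mouse build mm10. The role of each tool, the calling threshold and the use of IgG as a control are not given in the sources used here. Each file held the summits of 1 library, so peaks had been called per library and not on pooled samples. Whether the deposited −log10 value is of a p-value or a q-value is not stated. It grows with the depth of a library and had not been normalized between libraries, so it was used only to rank or select summits within a list.

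Summits were counted per library. Lists of different length are not comparable by overlap, so each H3K27ac list was limited to its 30000 highest-scoring summits for the overlap and presence comparisons, with ties broken at random under a fixed seed. DMSO replicate 2 had 53503 summits, of which 34928 shared its lowest score, so 11425 of its 30000 summits were a random draw among ties. A summit counted as shared when the other list had one within 250 bp. Consensus regions were the summits of the 7 limited lists extended by 250 bp on both sides and merged, which gave 60413 regions. A region or gene was gained when all 4 pracinostat lists and no DMSO list had a summit there, and lost when all 3 DMSO lists and no pracinostat list had one.

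Genes were taken from a table of the mouse reference assembly that mm10 names, with 21887 protein-coding genes on the numbered chromosomes, X and Y. The table gives the start and end of each gene without its strand or its transcription start sites. Promoter windows had been planned, and could not be placed. In their place, windows of 1 kb either side of both gene ends were used, one of which holds the gene's 5′ end. Genes with close ends share a window and cannot be told apart by it. A comparison with the 5′ end only had been set out and could not be run for the same reason. Windows moved by 100 kb gave the background rate of summits.

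For the rank comparison, full lists were used. A gene was given the highest summit score at its ends, genes with a summit in at least 3 of the 7 libraries were ranked within each library (13494 genes), and genes without a summit tied at the bottom. That tie took 37.9% of the ranked genes in DMSO replicate 2, against 6.84 to 11.2% in the other 6 libraries, which lifts the percentile of unmarked genes in that library. Genes whose highest score in DMSO replicate 2 was that library's lowest also tied, at a percentile of 47.3, Padi4 among them. A percentile of 100 is the highest score of the library. Ranks and lists of equal length are relative within a library, so a change of acetylation at all sites alike would not show in them. Percentiles were turned into normal scores, and pracinostat was compared with DMSO with limma 3.58.1 (trended, robust variance) in R 4.3.3 with statmod 1.5.0, with Benjamini-Hochberg adjustment. Regions were treated in the same way (48310 ranked). A difference of 1 normal-score unit corresponds to 1 SD of all ranked genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

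The 23 gene lists were fixed before the data were examined, as were the groups, the tests, most of the alternatives and the rule for named genes. Of 461 list genes 459 were in the gene table, 1 of them under an older symbol. The rule named the genes past the threshold, or up to 5 with the smallest p per direction, 8 gained and 8 lost genes with the highest percentile, the 2 members with the largest rise and the 2 with the largest fall in each list, 3 regions per direction, and Spi1, Csf1r, P2ry12, Ccr2, Itgam, Sirpa, Cdkn1a and Actb. Single values were compared with exact permutation tests over the 35 ways to split 7 libraries into 3 and 4, whose smallest p is 0.0286. The labels call the samples biological replicates and do not say which animal gave which library, so p-values measure the spread between these samples. The replicate numbers are shared between the groups; the fit with the number as a block was an alternative.

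The limma step was tested on simulated data made from the ranked values. With 13494 genes, 5.6, 59.2 and 77.6% of genes shifted by 1, 2 and 3 normal-score units were called. With 48310 regions, 0.333, 24.3 and 51.7% were called at the same shifts. Many genes or regions were shifted together in each run (500 genes and 300 regions per size over all runs). That eases the adjusted threshold, so a change standing alone would be called less often. A list of 20 genes was called in 0, 6 and 20 of 20 runs at shifts of 0, 0.25 and 0.5. A call there was a camera p under 0.05 divided by the number of lists. Genes in these runs varied independently, so the runs say nothing about false calls where genes of a list vary together. The presence step found all 200 gained and 150 lost regions planted in each of 5 simulated sets. These were planted in all lists of their own group and in no other list. The outcome therefore checks the counting and says nothing about power. Alternatives covered the number of summits kept, window and region widths, filters, quantile-normalized scores, array weights, list length as a covariate, other list tests and leaving out each library. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used, and figures were drawn with matplotlib 3.10.9.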

Results

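To ask how the histone deacetylase inhibitor pracinostat alters active chromatin in tumour-associated macrophages, H3K27ac was profiled in CD11b+ cells sorted from mouse brain tumours. NSG mice, an immunodeficient strain without mature lymphocytes, carried T387 human glioblastoma xenografts in the brain. Pracinostat (30 mg/kg by mouth) or DMSO vehicle was given 4 times a week for 3 weeks from day 7 after implantation. The labels conflict on the dose, since the text on how the drug was prepared gives 3 mg/kg. The study's title places these profiles beside a screen in which such inhibitors enhanced phagocytosis. There were 3 DMSO and 4 pracinostat libraries with H3K27ac antibody, and the same numbers with IgG.

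H3K27ac summits lay at 52.6 ± 12.1% (SD, n = 3) of protein-coding genes in DMSO libraries and 59.6 ± 1.45% (n = 4) in pracinostat libraries, counted within 1 kb of either gene end. Windows moved by 100 kb held a summit in 30.0 ± 15.0 and 37.5 ± 2.77% of cases. In the IgG libraries 1.85 ± 0.739% (DMSO, n = 3) and 0.891 ± 0.427% (pracinostat, n = 4) of gene ends had a summit, close to the 1.75 ± 0.751 and 0.835 ± 0.549% of moved windows. With H3K27ac antibody, gene ends therefore held a summit more often than windows moved by 100 kb in each library. With IgG they did so by a small margin in 5 of 7 libraries. These differences were not tested. H3K27ac libraries had 208401, 53503 and 291042 summits (DMSO replicates 1 to 3) and 236737, 229609, 246237 and 289017 (pracinostat replicates 1 to 4). IgG libraries had 18517, 9244 and 10191 (DMSO) and 2572, 10186, 6077 and 2194 (pracinostat). The ratio of geometric mean summits per library, H3K27ac over IgG, was 29.7 (two-sided exact permutation p = 0.000583 over the 3432 splits of 14 libraries). For summits per H3K27ac library, pracinostat over DMSO, the ratio was 1.68 (exact permutation p = 0.286), and 1.01 without DMSO replicate 2.

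**Figure D1:**
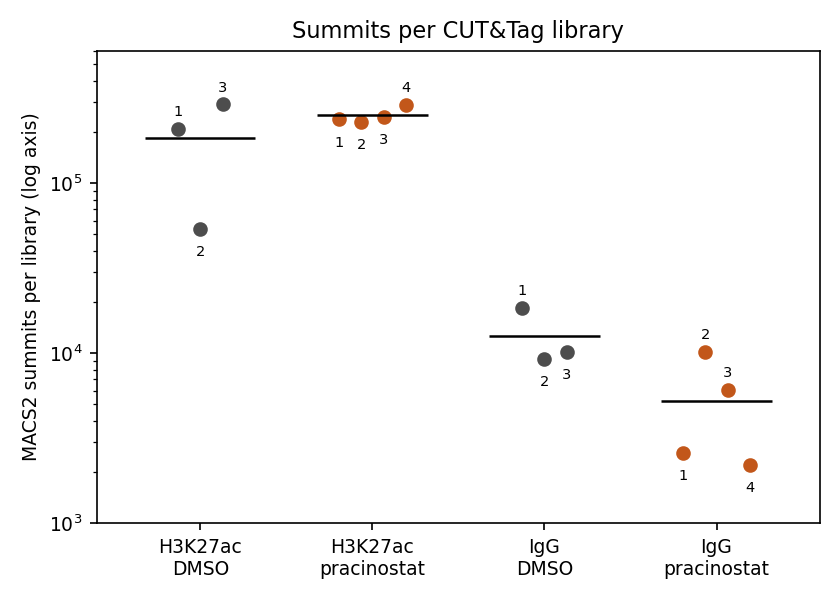
Number of MACS2 summits per library on a log axis, with each point a library marked by its replicate number and each line the mean of its group. All 7 H3K27ac libraries lie above all 7 IgG libraries, and DMSO replicate 2 has 53503 summits where the other H3K27ac libraries have 208401 to 291042.

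Among the fixed gene lists, lysosomal genes had the highest mean rank of H3K27ac summits in both treatments, an order that was not tested. Their ends had a mean percentile of 76.1 ± 1.25 in DMSO libraries (n = 3) and 76.7 ± 1.58 in pracinostat libraries (n = 4). MHC class I processing genes stood at 73.2 ± 4.12 and 73.6 ± 2.33, and transcription factors of the macrophage lineage at 70.2 ± 3.02 and 68.9 ± 2.09. Among single genes, Spi1, the transcription factor PU.1 that directs myeloid fate, had percentiles of 91.9 ± 3.43 and 90.9 ± 14.5. Csf1r, the receptor for the macrophage growth factor CSF1, stood at 66.3 ± 9.56 and 73.4 ± 10.0. Itgam, which encodes the CD11b antigen used for the sort, was at 39.8 ± 8.96 and 52.8 ± 10.1. Among lists of other cell types, lymphocyte markers had means of 26.9 ± 1.59 and 24.5 ± 4.16 over 9 ranked of 21 genes, neuron and astrocyte markers 26.9 ± 5.91 and 25.5 ± 4.11 over 7 of 18, endothelial and mural markers 23.7 ± 11.1 and 26.8 ± 6.67 over 6 of 14, and oligodendrocyte markers 39.6 ± 16.1 and 31.6 ± 2.53 over 5 of 12, with 58.0 in DMSO replicate 2.

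With full summit lists, markers of microglia, the resident macrophages of the brain, ranked higher with pracinostat, and markers of neutrophils ranked lower, in a call that most other settings ended. The mean percentile of 20 microglia genes was 52.0 ± 2.45 in DMSO libraries (n = 3) and 62.0 ± 4.503 in pracinostat libraries (n = 4), and 17 of the 20 were higher in the mean. Siglech, a lectin receptor of microglia that is also in the dendritic cell list, had percentiles of 34.8 ± 13.8 and 59.2 ± 11.5. Sparc, a secreted matrix protein, had 47.0 ± 37.9 and 65.2 ± 23.5, where DMSO replicate 3 at 3.83 set the direction (74.6 and 62.6 in the other DMSO libraries). Selplg and Trem2 had the largest falls in the list, from 54.4 ± 21.6 to 41.7 ± 3.63 and from 86.0 ± 8.07 to 75.9 ± 15.0. The mean over 15 neutrophil genes was 36.5 ± 3.88 in DMSO and 25.2 ± 3.86 in pracinostat libraries, with 13 of the 15 lower. Cxcr2, the chemokine receptor that draws neutrophils into tissue, had 45.7 ± 14.6 and 12.8 ± 6.87, and Padi4, which citrullinates histones in neutrophils, 34.4 ± 16.1 and 10.8 ± 5.33. S100a8 and Fpr1 were the exceptions, at 52.5 ± 6.08 against 56.3 ± 20.1 and 11.9 ± 7.63 against 17.1 ± 6.53. In both lists every pracinostat library lay beyond every DMSO library.

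Both lists passed limma's camera test at the preset correlation (adjusted p = 0.0214 for each, over 23 lists), and neither passed with an estimated correlation or with fry, which asks whether the genes of a list move one way on balance (adjusted p = 0.277 for each with an estimated correlation and 0.138 for each with fry). Adjusted over the list alone, 0 of the 20 microglia genes and 0 of the 15 neutrophil genes passed, as over all genes. At an unadjusted p under 0.05 there were 0 microglia genes and 3 neutrophil genes, namely Cxcr2, Padi4 and Camp, the last of which was named after its values were seen. An exact permutation of the list means gave p = 0.0571 for the microglia list and 0.0286 for the neutrophil list, the smallest this design allows, and 0.438 for both after adjustment. Over 23 lists even that smallest p cannot pass unless many lists reach it, so the adjusted values decide nothing. Without DMSO replicate 2 both calls ended (camera adjusted p = 0.142 for each), with differences of 8.61 and −9.04 percentile points where the full set gave 10.0 and −11.3. The microglia call also ended without DMSO replicate 1 or 3 and without pracinostat replicate 1 or 3, and the neutrophil call without pracinostat replicate 3. With lists of equal length both calls ended (camera adjusted p = 0.155 for each), with differences of 0.308 ± 0.129 (SE) and −0.526 ± 0.224 normal-score units over 18 and 6 ranked genes, where full lists gave 0.292 ± 0.0738 and −0.361 ± 0.0905. With list length as a covariate both ended as well (adjusted p = 0.136 for each), at 0.277 ± 0.0921 and −0.284 ± 0.0800. In the same units, leaving out DMSO replicate 2 gave 0.277 ± 0.0924 and −0.285 ± 0.0790. List length mainly sets that library apart, so the covariate is not a separate check. Over 19 alternatives in all, among them windows of 500 bp and 2.5 kb, the microglia list passed in 6 and the neutrophil list in 8, and neither turned its direction.

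**Figure D2:**
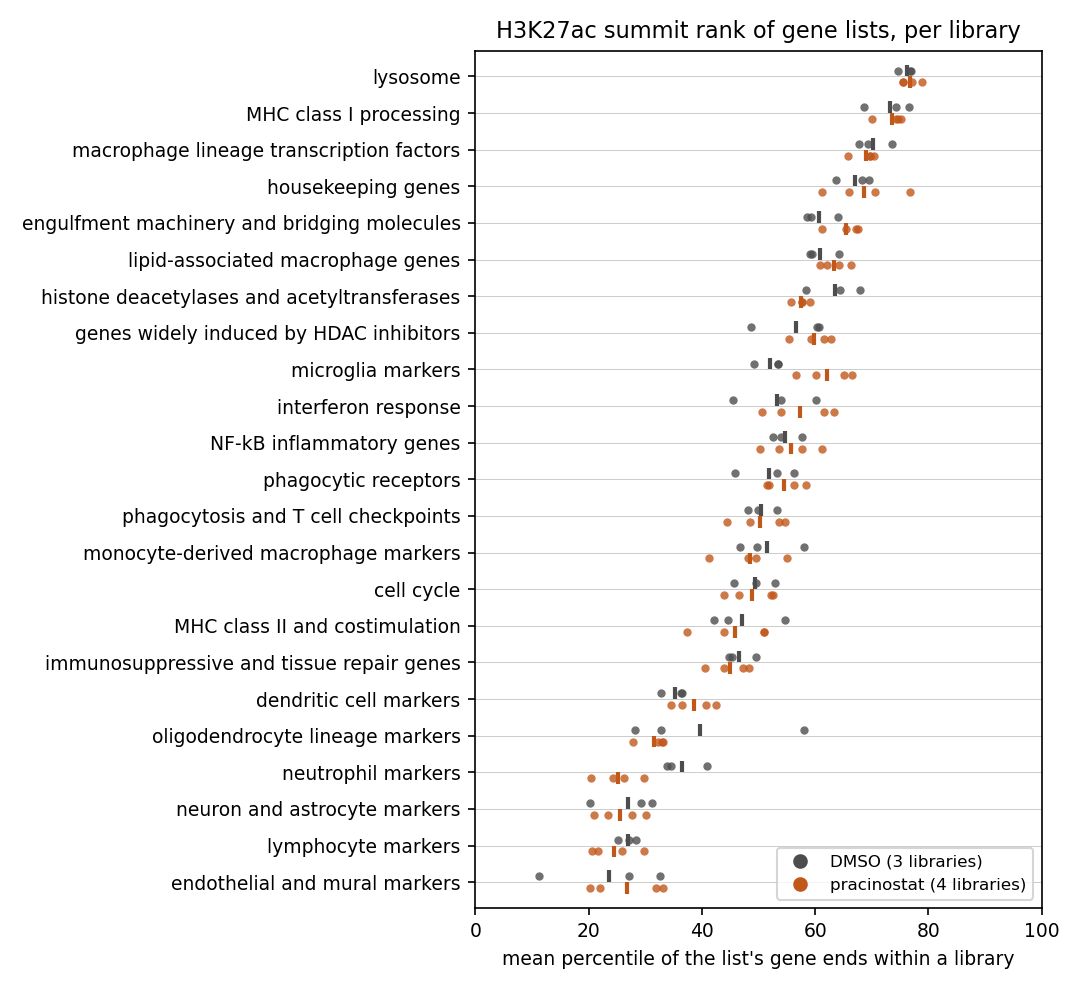
Mean within-library percentile of the H3K27ac summits at the gene ends of each fixed list, 1 point per library (grey DMSO, orange pracinostat), with a bar at each group mean. Lysosomal genes are highest in both groups, and the groups separate for microglia markers (52.0 against 62.0) and neutrophil markers (36.5 against 25.2).

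Genes of phagocytosis showed no difference that passed. Engulfment machinery genes had mean percentiles of 60.6 ± 2.96 with DMSO (n = 3) and 65.4 ± 2.90 with pracinostat (n = 4), with 18 of 26 higher (camera adjusted p = 0.457). Dock2, an activator of Rac in blood cells, had 50.3 ± 2.63 and 82.3 ± 13.1, and Syk, a kinase downstream of Fc receptors, 84.7 ± 0.571 and 61.3 ± 9.28. Phagocytic receptors had means of 51.8 ± 5.35 and 54.5 ± 3.39, with 15 of 25 higher (adjusted p = 0.736), and their difference of 2.69 turned to −0.277 without DMSO replicate 2. The inhibitory Fc receptor gene Fcgr2b had 40.7 ± 19.3 and 70.3 ± 24.7, the high-affinity activating receptor gene Fcgr1 34.2 ± 14.4 and 60.6 ± 21.2, and the scavenger receptor gene Scarb1 85.5 ± 14.8 and 63.8 ± 9.11. Checkpoint genes of phagocytosis and T cells had means of 50.4 ± 2.57 and 50.3 ± 4.76, with 9 of 18 higher (adjusted p = 0.849), and a difference of −0.141 that was −1.30 without DMSO replicate 2. Within that list Cd274, which encodes PD-L1, had 84.3 ± 9.61 and 95.03 ± 4.98, and Sirpa, the receptor for the CD47 signal, named in advance, 58.5 ± 15.0 and 65.5 ± 19.8. In these 3 lists 0 genes passed in limma over all genes and 0 adjusted over the list alone, and at an unadjusted p under 0.05 there were 1 engulfment gene, 3 receptor genes and 0 checkpoint genes. Beside them the neutrophil list differed by −11.3 percentile points (−9.04 without DMSO replicate 2, camera adjusted p = 0.277 with an estimated correlation).

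Across the other lists, 1 gene passed when adjusted over the list alone. Lipa, which encodes lysosomal acid lipase, had percentiles of 75.6 ± 25.7 with DMSO and 99.1 ± 0.926 with pracinostat, with limma adjusted p = 0.0364 over the lysosome list, 0.0259 over the lipid-associated macrophage list and 0.571 over all genes. Both list calls ended without DMSO replicate 1 or 3 and without pracinostat replicate 2 or 4, and without DMSO replicate 3 the gap went from 23.5 to 9.46 percentile points (adjusted p = 0.589 and 0.391). Lysosomal genes as a group gave camera adjusted p = 0.796 (16 of 31 higher) and lipid-associated macrophage genes 0.457 (15 of 22 higher), where Pparg, a lipid-sensing nuclear receptor, had 41.4 ± 9.82 and 12.7 ± 12.1. Histone deacetylases and acetyltransferases had means of 63.6 ± 4.83 and 57.6 ± 1.38, with 18 of 24 lower (adjusted p = 0.319). Genes widely induced by inhibitors of these enzymes had 56.6 ± 6.82 and 59.8 ± 3.24, with 5 of 9 higher (adjusted p = 0.849). Cdkn1a, the cell cycle inhibitor gene often used as a readout of such drugs, was at 32.2 ± 11.5 and 32.4 ± 11.7. A rise in acetylation at all sites alike would leave within-library ranks unchanged, so these values do not test for it. Interferon response genes had 53.2 ± 7.39 and 57.4 ± 6.02 (adjusted p = 0.457), NF-kB inflammatory genes 54.7 ± 2.62 and 55.7 ± 4.77 (0.796), immunosuppressive and tissue repair genes 46.6 ± 2.58 and 45.0 ± 3.58 (0.796) and MHC class II genes 47.1 ± 6.66 and 45.8 ± 6.58 (0.849). Monocyte-derived macrophage markers had 51.5 ± 5.88 and 48.5 ± 5.72 (0.796), with Ccr2, the receptor that recruits monocytes, at 30.4 ± 11.7 and 17.3 ± 15.0. Dendritic cell markers had 35.2 ± 2.06 and 38.6 ± 3.69 (0.796), cell cycle genes 49.4 ± 3.65 and 48.8 ± 4.26 (0.927) and housekeeping genes 67.1 ± 3.08 and 68.6 ± 6.64 (0.796). The remaining lists gave adjusted p = 0.849 (MHC class I processing, macrophage transcription factors, lymphocyte markers, and neuron and astrocyte markers), 0.796 (endothelial and mural markers) and 0.457 (oligodendrocyte markers). Beside these, the neutrophil list differed by −11.3 percentile points (−9.04 without DMSO replicate 2, camera adjusted p = 0.277 with an estimated correlation). Without DMSO replicate 2 the differences of the oligodendrocyte, macrophage transcription factor, cell cycle, MHC class I and housekeeping lists turned to 1.12, 0.394, 1.16, −1.90 and −0.210, and those of the interferon, neuron and astrocyte, NF-kB, deacetylase and acetyltransferase, and dendritic lists shrank to 0.285, −0.195, 0.552, −3.78 and 2.17. Those of the endothelial and mural, MHC class II, monocyte-derived, inhibitor-induced and lysosome lists grew to 7.598, −2.61, −5.45, 5.06 and 0.930. In the lists of MHC class II, MHC class I and macrophage transcription factors the median difference had the opposite sign to the mean and the test, and in the checkpoint list the difference in mean percentile alone did (−0.141).

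At single gene ends the largest evidence was at Nampt, the rate-limiting enzyme of NAD salvage, which stood lower with pracinostat. Nampt (chromosome 12, 32820335 to 32853369, mm10) had a percentile of 97.4 ± 4.00 in DMSO libraries (n = 3) and 55.0 ± 18.6 in pracinostat libraries (n = 4), a difference of −2.16 ± 0.422 (SE) normal-score units that did not pass (limma adjusted p = 0.0709). After it among the lower genes came Ube3c, a ubiquitin ligase (89.3 ± 12.0 and 42.3 ± 13.7), Armc6 and Sugp2, which share a window (90.4 ± 6.74 and 47.0 ± 14.9), and Tada2a, an adaptor of histone acetyltransferase complexes that shares a window with Acaca (55.3 ± 16.4 and 12.1 ± 8.62). The smallest p among the higher genes belonged to Dcaf10, a substrate receptor of a ubiquitin ligase (9.47 ± 8.28 and 59.5 ± 23.1), Trim41, which shares a window with Rack1 (38.0 ± 29.9 and 88.1 ± 8.47), Stum (18.5 ± 9.28 and 68.7 ± 24.4), Pcgf2, a Polycomb protein whose window also holds ends of Cisd3 and Psmb3 (40.6 ± 25.9 and 89.4 ± 4.79), and Zfp970 (21.3 ± 17.1 and 68.4 ± 16.1). Their adjusted p-values lay between 0.216 and 0.488.

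Of 13494 gene ends, 0 passed in limma on within-library ranks, and 832 had an unadjusted p under 0.05, 370 higher and 462 lower. Other groupings of the 7 libraries gave 432 to 990, and 4 of them gave more. The housekeeping gene Actb had 77.8 ± 10.8 and 74.8 ± 11.9, and P2ry12, a microglial purine receptor, 56.9 ± 25.0 and 63.9 ± 22.0. Nampt was lower in 17 of 17 alternatives and passed in 6, among them without DMSO replicate 3 (adjusted p = 0.00749) and without pracinostat replicate 2 (0.0316). It did not pass without DMSO replicate 1 or 2 or without pracinostat replicate 1, 3 or 4. The lowest limma adjusted p of any gene there was 0.104 to 0.684. Leaving out DMSO replicate 3 also called Trim41 higher and Ube3c and Caap1 lower (adjusted p = 0.0415 for each), and counting genes with any summit called Dcaf10 (0.0115). Of the 5 higher genes, 4 depended on the window and Zfp970 did little (1.29 to 1.74 normal-score units). Dcaf10 went from 1.70 to −0.145 normal-score units with 2.5 kb windows and −0.158 over the whole gene, Pcgf2 from 1.59 to 0.0846 and 0.647 with 500 bp and 2.5 kb windows and 1.40 over the whole gene, and Trim41 from 1.69 to 0.863 and 0.462 with 500 bp and 2.5 kb windows. Stum went from 1.49 to 1.43 and 1.11 with these windows and to 0.766 over the whole gene.

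**Figure D3:**
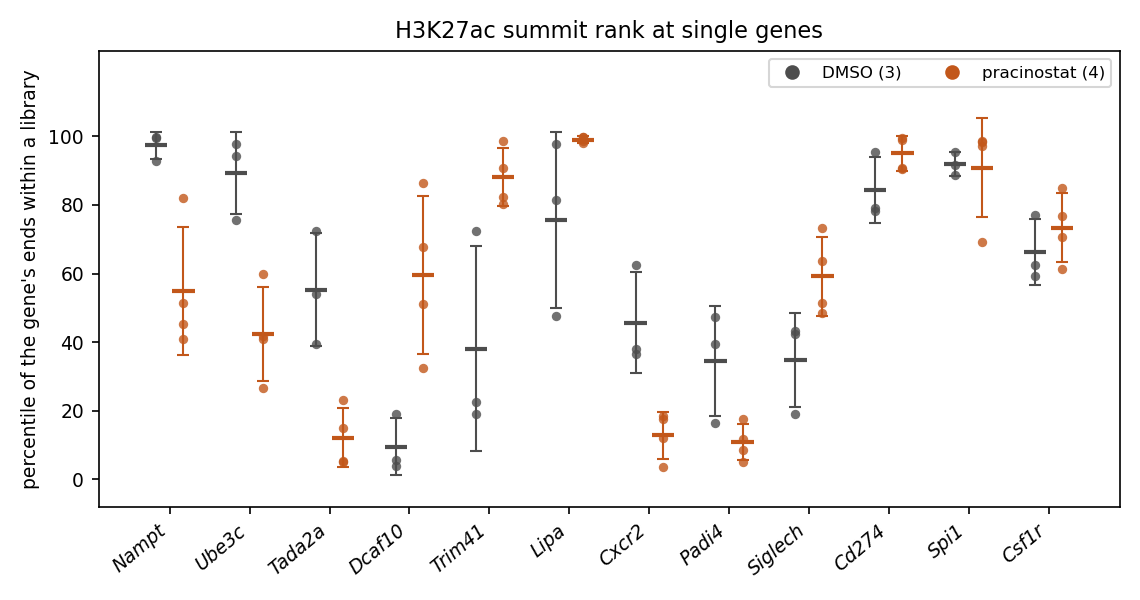
Within-library percentile of the strongest H3K27ac summit at the ends of 12 genes, with 1 point per library, bars at the mean and error bars of 1 SD (grey DMSO, n = 3, orange pracinostat, n = 4). Nampt lies at 97.4 and 55.0, Lipa at 75.6 and 99.1 and Cxcr2 at 45.7 and 12.8 in the 2 groups, and an SD bar can pass 100, which no value does.

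Among consensus regions, 1 ranked lower and 1 higher with pracinostat. The lower one, on chromosome 12 from 32819493 to 32820384, overlaps an end of Nampt. Its percentile was 99.0 ± 1.61 in DMSO (n = 3) and 64.5 ± 19.3 in pracinostat libraries (n = 4; −2.21 ± 0.422 normal-score units, limma adjusted p = 0.00787), and 0 IgG libraries had a summit in it. The higher one, on chromosome 5 from 3493951 to 3495160, lies inside Cdk6, which encodes a kinase of the G1 phase, 35848 bp from its nearer end (67.2 ± 37.0 and 97.5 ± 4.47, adjusted p = 0.0358). Next in order, and not past the threshold, were regions at Cttnbp2nl (55.8 ± 28.0 and 97.1 ± 2.47) and Ncbp3 (15.1 ± 8.71 and 76.96 ± 19.4), which were higher, and in Pde4c (76.4 ± 36.2 and 17.2 ± 9.49) and Trim16 (78.0 ± 15.2 and 8.73 ± 1.52), which were lower. Of 48310 regions 2489 had an unadjusted p under 0.05, where other groupings gave 1499 to 2677 and 2 of them gave more. Without DMSO replicate 2 there were 0 calls (adjusted p = 0.398 for Nampt and 0.993 for Cdk6, with differences of −2.03 and 1.34). With list length as a covariate both calls ended as well (adjusted p = 0.397 and 0.985, differences −1.86 ± 0.45 (SE) and 1.43 ± 0.439), and with array weights that of Cdk6 (0.365). The Nampt call also ended without DMSO replicate 1 and without pracinostat replicate 1 or 3, and the Cdk6 call without DMSO replicate 3 and without pracinostat replicate 1, 2 or 3. The Cdk6 region had no summit in DMSO replicate 2.

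By presence alone, 169 of 60413 regions were gained and 99 lost with pracinostat. At gene ends, 34 genes were gained, among them Dnajc18, Ttc1, Cbx8, a Polycomb protein, Ppm1k, Cklf, a chemokine-like factor, Eif3c, and Ttc37 and Arsk, which share a window. The 31 lost genes included Agtpbp1, Kansl3, a member of a histone acetyltransferase complex, Pdpk1 and Kctd5, which share a window, Gtpbp10, Zbtb1, which shares a window with Zbtb25, Zfp282 and Gm46608, which shares one with Qk. Dnajc18 had percentiles of 28.8 ± 12.1 and 76.7 ± 14.9, and Kansl3 73.1 ± 15.9 and 32.6 ± 4.74. The counts were larger than in most other groupings of the libraries and did not pass (exact permutation p = 0.171 for regions and 0.2 for gene ends over 35 splits). With 53503 summits per list, the length of the shortest, the real grouping gave the highest count (282 regions gained and 176 lost, 34 and 23 genes, exact permutation p = 0.0286 for each, the smallest possible), and with 10000 or all summits it did not (p = 0.229 and 0.429 for regions). More gains than losses were not kept with 10000 summits. Regions gained were then 68 and regions lost 70, and gene ends gained 27 and gene ends lost 40. Regions lost also outnumbered regions gained without DMSO replicate 2 (392 and 273) or 3 (496 and 421). Gene ends lost also outnumbered those gained without DMSO replicate 2 (69 and 68) or pracinostat replicate 2 (76 and 47) or 4 (58 and 56). For gene ends the same held over the whole gene span (29 and 26) and above the lowest score of the shortest list (39 and 31). In both counts, leaving out any other library kept more gains than losses.

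**Figure D4:**
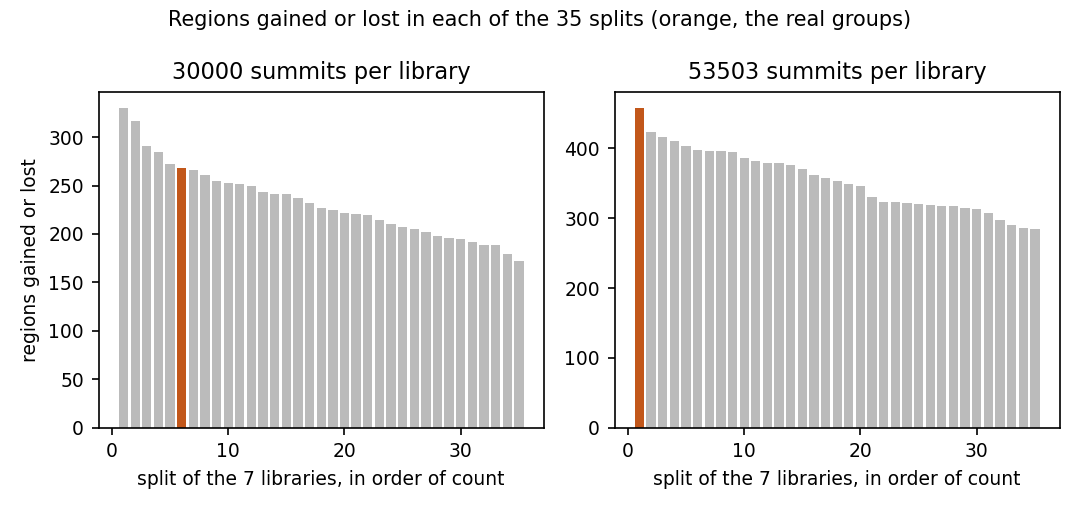
Number of consensus regions gained or lost in each of the 35 splits of the 7 H3K27ac libraries into 4 and 3, in order of size, with 30000 summits per library (left) and 53503 (right). The real grouping (orange) has 268 regions on the left, where another split reaches 330, and 458 on the right, where the highest other split has 423.

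The overlap of summit lists did not separate the treatments. Lists of 2 libraries of 1 treatment shared 49.2% of their summits on average (9 pairs) and lists of different treatments 46.6% (12 pairs), a difference of 2.57 percentage points (one-sided exact permutation p = 0.143). Pairs that included DMSO replicate 2 shared 32.8% and the other 15 pairs 53.6%. The overlap of summit lists, within minus between treatments, was 0.190 points without that library, 8.79 without DMSO replicate 1, 7.07 without DMSO replicate 3 and below 0 without pracinostat replicate 1 or 4. All 7 libraries had a summit in 5047 regions, and 32721 regions were marked in 1 library. Of the 30000 highest summits, 33.2 ± 6.67% (n = 3, DMSO) and 35.4 ± 2.70% (n = 4, pracinostat) lay within 1 kb of a gene end (two-sided exact permutation p = 0.657). The share of summits at gene ends, pracinostat minus DMSO, was 2.22 points and turned to −1.42 without DMSO replicate 2, −1.21 with 10000 summits per list and −2.29 with full lists. An IgG summit lay in 0.434 ± 0.145% of consensus regions in DMSO libraries (n = 3) and 0.282 ± 0.128% in pracinostat libraries (n = 4; exact permutation p = 0.2), against 0.321 ± 0.13 and 0.173 ± 0.114% of moved regions.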

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

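Leaving out DMSO replicate 2, list length as a covariate, equal length and the splits of the presence counts were planned as alternatives or tests. Their use against these explanations, with its bounds, was chosen after the results were seen. The same holds for the splits of the list and region calls and the comparison of the other myeloid lists. The test of distant regions was written before its result, and its bound was made stricter afterwards.

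In 3 of 31 sets of 4 pracinostat libraries 1 library stood apart from the other 3, where chance gives about 1 in 20. MHC class I processing genes had a mean percentile of 70.1 in replicate 2, against 74.3 to 75.1 in the others. Oligodendrocyte markers had 27.8 in replicate 3, against 32.3 to 33.1, over 5 ranked genes. Macrophage transcription factors had 65.8 in replicate 4, against 69.7 to 70.5.

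Microglia markers were higher and neutrophil markers lower with pracinostat by camera at its preset correlation (adjusted p = 0.0214 for each), and neither passed with an estimated correlation (0.277 for each) or fry (0.138 for each). Chance cannot be excluded: 2 of the 35 splits of the 7 libraries, the real one included, gave at least 2 lists past the threshold, and the highest other split gave 3. Further splits gave 1 list. The short list of DMSO replicate 2 does not explain the whole size of the differences, which were at least 0.802 ± 0.175 (SE) of the full ones in percentile points without it and, in normal-score units, at least 0.786 ± 0.221 with list length as a covariate and 1.06 ± 0.441 at equal length, although each of these settings ended both calls. Compared with the full differences in normal-score units, the error of the microglia list was wider in each of these settings. That of the neutrophil list was wider at equal length, where 6 of its genes were ranked. In the other settings the neutrophil difference was smaller than its full one. The covariate and the left-out library gave nearly the same list differences and are not separate checks. Fewer neutrophils with all else unchanged stays open: the differences of the microglia, monocyte-derived and dendritic lists lay 13.1 percentile points apart, and another split reached 13.6 (exact permutation p = 0.0571). A shift in the mix of sorted CD11b+ cells and a change of acetylation within cells cannot be told apart here. Regions away from gene ends near neutrophil genes differed by −0.0342 normal-score units (exact permutation p = 0.686), and by 0.0255 without DMSO replicate 2. Those near microglia genes differed by 0.0916 (exact permutation p = 0.286). The bound written before the result asked for the signs alone, a fall near neutrophil genes and a rise near microglia genes. Both signs went with a shift in the mix in the full set, and the neutrophil sign turned without DMSO replicate 2. The p was added to the bound after the result was seen, and neither p was under 0.05.

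The region at Nampt was lower with pracinostat. Chance cannot be excluded, since 5 of the 35 splits, the real one included, gave at least the 2 regions past the threshold of the real grouping, and the highest other split gave 3. The short list of DMSO replicate 2 is not its whole cause: the difference was 0.918 ± 0.222 (SE) of the full one without that library and 0.844 ± 0.204 with list length as a covariate. The call ended in both (adjusted p = 0.398 and 0.397). An effect of the drug on this gene stays open and was not tested apart from the grouping.

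For regions gained and lost, 6 of the 35 splits, the real one included, gave at least the 268 of the real grouping, with 330 the highest other, and for gene ends 7 gave at least 65, with 79 the highest other, so chance cannot be excluded for either with 30000 summits per list.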

How the results depend on the processing

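Limiting the lists above the lowest score of the shortest list and the whole gene span were chosen after the data were seen; the other alternatives were planned. The planned window at the 5′ end only was not run, since the gene table has no strand. Without 1 library, summits per H3K27ac library, pracinostat over DMSO, ranged from 1.01 to 2.36, summits per library, H3K27ac over IgG, from 24.7 to 37.0, and consensus regions with an IgG summit, pracinostat minus DMSO, from −0.209 to −0.0679. These 3 kept their direction. For the first and the third the threshold could not be crossed with 1 library left out, since the smallest exact p is then 0.0667. Where a cause is not named, it was not tested.

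The share of summits at gene ends, pracinostat minus DMSO, turned to −1.21 with 10000 summits and −2.29 with full lists, and ranged from −1.42 to 5.12 without 1 library. The overlap of summit lists, within minus between treatments, ranged from −0.173 to 8.79 without 1 library and was below 0 without pracinostat replicate 1 or 4. The number of regions gained was 68, 282, 1582 and 100 with 10000 summits, the length of the shortest list, full lists and summits above its lowest score, and 273 to 528 without 1 library, where fewer libraries have to share a state. The number of regions lost was 70, 176, 239 and 80 in the same order, and 147 to 519 without 1 library. The number of gene ends gained was 27, 34, 72 and 31 and 47 to 127 without 1 library, and that of gene ends lost 40, 23, 5 and 39 and 41 to 90. Gene ends lost outnumbered those gained with 10000 summits, above the lowest score and over the whole gene span (29 and 26). The same held without DMSO replicate 2 (69 and 68), pracinostat replicate 2 (76 and 47) or pracinostat replicate 4 (58 and 56). Regions lost outnumbered regions gained with 10000 summits and without DMSO replicate 2 (392 and 273) or 3 (496 and 421). In each case, leaving out any remaining library kept more gains than losses.

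Gene-end calls were 1 higher and 1 lower with no filter, 2 lower with 500 bp windows (Nampt and Ppp2r5c), 1 lower with a summit in all 7 libraries and 1 lower with the shortest length, and 0 to 1 higher and 0 to 3 lower without 1 library. Region calls were 0 higher with a summit in all 7 libraries and with array weights, 0 in either direction with list length as a covariate, 2 lower with 500 bp extension, and 0 to 1 higher and 0 to 2 lower without 1 library. The number of lists was 0 higher and 0 lower with 500 bp and 2.5 kb windows, a summit in all 7 libraries, the shortest length, list length as a covariate, the whole gene span, an estimated correlation, fry and the exact permutation, and 0 lower with no filter. The exact permutation could not call a list here unless many lists reached its smallest p of 0.0286. Its outcome therefore decides nothing. Without 1 library it was 0 to 1 in each direction. Over 19 alternatives of camera and fry the microglia list passed in 6 (adjusted p 0.0137 to 0.595) and the neutrophil list in 8 (0.00941 to 0.412), with no change of direction. The region at Nampt passed in 7 of 13 (0.00138 to 0.398) and that in Cdk6 in 5 of 12 (0.00176 to 0.993). The region at Pde4c passed with 500 bp extension (adjusted p = 0.0147) and without DMSO replicate 1 (0.00314). Named genes that passed in neither setting changed sign in 70 of 1996 values and lists in 41 of 425; these were not counted as reversals.

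Same-numbered libraries of the groups did not deviate together (correlations across genes of −0.0544, 0.000524 and −0.0235), so the numbers were not taken as pairs. With the replicate block the overlap of summit lists, within minus between treatments, was −0.0199, regions gained were 321 and regions lost 149, gene ends gained 56 and gene ends lost 58 (replicates 1 to 3, which drops pracinostat replicate 4), gene-end calls 0 and 0, region calls 1 higher and 0 lower, and lists 1 higher and 1 lower.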

Other observations

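The genes below were picked, after their values were seen, from the 40 with the most summits among the 30000 highest of a library. Summits were counted over the gene and 10 kb on both sides. Zmiz1, a transcriptional coregulator, held the most, 74.1 ± 14.2 summits per library (SD, n = 7). Next in order were 3110082I17Rik (45.9 ± 7.22), Tns3 (42.1 ± 5.40) and Zfp710 (39.4 ± 3.41). Further down, Etv6 held 37.0 ± 7.30, Rxra, a nuclear receptor, 35.9 ± 8.97, and Lrp1, a receptor for the engulfment of dying cells, 33.9 ± 3.53. Inpp5d, a phosphatase of blood cells, held 26.0 ± 6.08 and Spi1 26.1 ± 6.77. Long genes can hold more summits. Per 10 kb, Spi1 held 4.90, Zmiz1 3.24, Inpp5d 2.16 and Etv6 1.45, and of the 40 genes with the most summits Gpr146 (7.79), Aldh3b1 (7.49) and Prkcd, a kinase of myeloid signalling (6.13), were densely marked. Itpkb, which limits calcium signals in immune cells, had 23 ± 1.73 summits in DMSO libraries (n = 3) and 33.8 ± 1.89 in pracinostat libraries (n = 4), a difference that was not tested.

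Regions away from gene ends, within 20 kb of the genes of each list, were compared in 23 exact permutation tests, and none passed after adjustment (lowest adjusted p = 0.548). The smallest p of each test is 0.0286, so no list could pass over 23 tests unless many reached it together. The lack of a pass therefore decides nothing. Those near phagocytic receptor genes had mean percentiles of 46.8 ± 1.19 with DMSO (n = 3) and 50.2 ± 1.87 with pracinostat (n = 4) over 252 regions (exact permutation p = 0.0571). Those near endothelial and mural genes had 45.1 ± 3.18 and 38.6 ± 3.00 over 30 regions (exact permutation p = 0.0571). In DMSO replicate 2 the oligodendrocyte list stood at 58.0, where the other 6 libraries lay between 27.8 and 33.1.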
